A study of Homo sapiens with 6 samples.

How the data were processed

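RNA was sequenced from CD34+ cells of human umbilical cord blood in 6 libraries, 3 wild type and 3 YTHDF2 knockdown. Per the labels' protocols, the libraries came from a kit that does not record strand and were read as single ends of 76 bases on a NextSeq. The submitters' processing notes name bcl2fastq 2.18.0.12, TopHat2 2.0.13, HTSeq, edgeR 3.18.1 and the genome build hg38, with no role or order. The annotation used for counting is not given in the sources used here. Groups were taken from the sample titles, and the columns headed as controls were matched to wild type by name and number.

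The deposited values are a per-gene signal, counts that the authors scaled by a factor per sample and rounded to 3 decimals. They are neither raw counts nor plain CPM, since the columns sum to between 652107 and 1464900. In each column the values were whole multiples of the value of 1 read: 100% came out whole within 0.1 read. The totals so recovered ranged from 49957257 to 59209652 reads, so counting error is small beside the spread between libraries for all but low genes. The factors implied by the steps were 1.47, 1.53 and 1.03 for wild type and 0.972, 0.683 and 0.860 for knockdown, and their product was 1.33 rather than the 1 that edgeR's factors give. How the authors obtained them is not given in the sources used here.

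The table held 57992 gene identifiers, of which 57388 had a record in GENCODE release 29 (GRCh38), the source of symbols and coordinates. For the privacy of donors, 527 sex-linked genes and 543 genes that follow common polymorphisms were left out, which with no other filter left 56922. Genes with a mean deposited value of at least 1 over the 6 libraries, 14023 in all, were tested. A gene near the floor in 1 group could thus pass through its values in the other.

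The main test, fixed before the data were examined, was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(value + 1), with the group as the only term, two-sided, and Benjamini-Hochberg adjustment at 0.05. Fold changes are knockdown minus wild type on the log2(value + 1) scale, which understates the change of low genes. The design had assumed normalized values, and this test fits the unit found. Because the deposited scaling shifted nearly all genes together, the text leads with the values rescaled by TMM factors from edgeR 4.0.16, an alternative also fixed beforehand. Any such rescaling assumes that most genes do not change, so a true rise in RNA per cell would be removed with the shift.

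The 26 gene lists were fixed beforehand and tested with camera in limma at a preset correlation between genes of 0.01, with adjustment over the lists, and again with an estimated correlation. The test with an estimated correlation also rests on the 4 residual degrees of freedom, so a call lost there is not due to correlation alone. The T and NK list had an estimated correlation of -0.061 after TMM, yet its camera adjusted p went from 0.00831 to 0.340. As deposited the estimates, such as 0.986 for ribosomal protein genes, also hold the library shift shared by all genes. Camera compares a list with all other genes. On log2(value + 1) a change of scaling moves low genes less than high ones, so it does not cancel fully: the mean difference of ribosomal protein genes was -0.151 as deposited and -0.237 after TMM. Genes were named by a rule fixed beforehand. It took YTHDF2, the 10 largest changes up and down past the threshold with groups that do not overlap and a mean of at least 5, up to 4 members of each list with the smallest p-value in the deposited fit, and TAL1, GATA2, RUNX1, STAT5A and MYC. Since the deposited fit favours higher genes, the members named for a list lean towards those that rose.

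Alternatives were pseudocounts of 0.25 and 5, no filter and a stricter filter with a mean of 5, TMM, median-of-ratios, equal totals and quantile scaling, limma without the trend or with array weights, edgeR's quasi-likelihood test and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, each library left out in turn, an adjusted p of 0.1, and for lists also fry. Added after seeing the data were the count tests with their own scaling, removal of a length and GC trend (splines with 5 degrees of freedom), and leaving out libraries after TMM. On the recovered reads with the authors' scaling, edgeR called 8913 genes and DESeq2 9866. A result was counted as reversed only where the value or its alternative passed the threshold. The check on other splits of the samples used the 10 splits of 6 libraries into 3 and 3.

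Replicates were compared before averaging. The chi-square per gene between libraries of a group was 6.03 to 25.5, highest for wild type replicate 2 against the other wild type libraries, and 176 to 209 between groups, so no pair agreed within sampling noise. The steps were tested on simulated counts for the 14023 genes, 3 against 3. After TMM, 76.1%, 91.0% and 100% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 0.058% of unchanged genes called. With the deposited scaling the shares were 0%, 67.2% and 100%, with 0% of unchanged genes called. The simulated libraries kept the shifts within a group but not the one between groups. These deposited shares therefore do not describe the real deposited values, where the median gene differs by 0.67 (log2) between groups. In the simulation 13823 of the 14023 genes were unchanged, so the assumption behind TMM held by construction. The TMM shares therefore do not test that assumption on the real values. Of the simulated lists, the 1 that was raised was found and none of 39 unchanged lists was called. Genes in the simulated lists were drawn at random and varied independently. This therefore does not test the preset correlation on lists whose members vary together. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for reading and plotting.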

Results

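RNA was measured by sequencing in CD34+ haematopoietic stem and progenitor cells, the immature blood-forming cells, from human umbilical cord blood. The cells were grown with interleukin 6, stem cell factor, FLT3 ligand and thrombopoietin, and CD34+ cells carrying green fluorescent protein were sorted for RNA. There were 2 groups of 3 libraries, wild type and YTHDF2 knockdown. YTHDF2 is a protein that binds mRNA carrying N6-methyladenosine (m6A) and promotes its decay, so the comparison asks how the transcriptome of these progenitors differs when YTHDF2 is reduced. The whole reads recovered from the deposited values came to 55575017, 56825018 and 59209652 in wild type replicates 1 to 3 and to 49957257, 55026874 and 54909405 in knockdown replicates 1 to 3. The labels do not say whether the replicates are separate donors or cultures, so p-values measure only the spread between these samples, which may be technical. They also do not name a vector, or say whether the wild type cells carried one. If the sort for green fluorescent protein covered both groups, wild type cells carried a construct too, but which one is not stated. Any difference between the groups may therefore hold an effect of the vector.

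YTHDF2 itself (ENSG00000198492, chromosome 1, 28736621 to 28769775, plus strand, GRCh38) was lower in all 3 knockdown libraries than in any wild type library. Its deposited value was 152, 161 and 219 in wild type replicates 1 to 3, and 37.2, 55.5 and 46.2 in knockdown replicates 1 to 3. The group values were 177 ± 36.5 (SD, n = 3) and 46.3 ± 9.11 (SD, n = 3). The log2 fold change was -1.91 with a standard error of 0.27 (limma adjusted p = 5.98e-11). Rescaled with TMM (trimmed mean of M values) factors, it was -2.70 with a standard error of 0.07 (limma adjusted p = 8.40e-13). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries allow.

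The knockdown libraries held more embryonic and fetal globin RNA than wild type. HBE1, the embryonic epsilon globin, rose from 52.9 ± 26.5 to 3202 ± 843 in the deposited values (SD, n = 3 each), 62.6-fold, and 36.3-fold after TMM rescaling. HBG2, a fetal gamma globin, rose from 181 ± 47.7 to 3815 ± 846 (SD, n = 3 each), 21.1-fold, and 12.2-fold after TMM. ELANE, neutrophil elastase, and ENPP3, a mast cell and basophil surface enzyme, were lower. Of 22 granulocyte genes, 18 fell and 3 rose after TMM rescaling (10 lower and 3 higher as deposited), and of 21 mast cell, basophil and eosinophil genes 17 fell and 1 rose (6 lower and 3 higher as deposited). The calls for both lists were lost with an estimated correlation between genes (adjusted p = 0.708 and adjusted p = 0.340 after TMM, and adjusted p = 0.985 for each as deposited, with an estimated correlation).

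The size and often the direction of a change depended on how the libraries were scaled. The deposited columns summed to 678467, 652107 and 970966 in wild type and to 1029030, 1464900 and 1163110 in knockdown, although wild type libraries held slightly more reads. The median gene was therefore 0.67 (log2) higher in the knockdown, and 93.3% of the 14023 genes tested lay above 0. The median gene per library, against the mean of the 6, was -0.33 ± 0.30 in wild type and 0.34 ± 0.24 in knockdown (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible). Changes are given below after TMM rescaling, which takes this shared shift away, with the deposited value beside them where the direction differs.

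**Figure D1:**
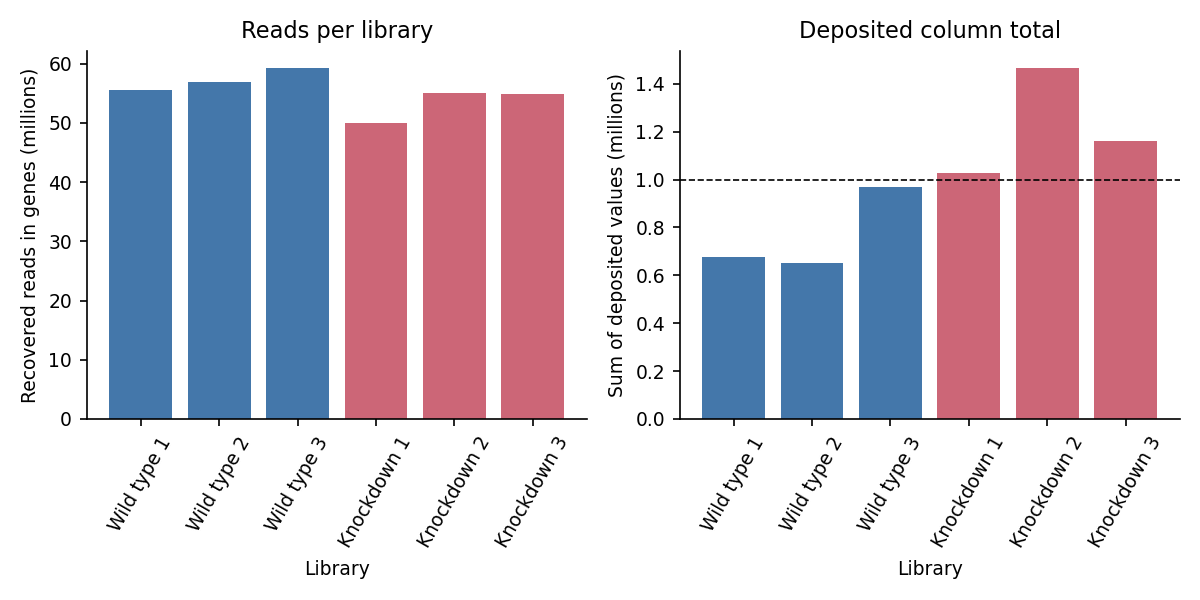
Left, whole reads recovered per library, on an axis in units of 1e6 reads; right, the sum of each deposited column on the same unit, with a dashed line at 1. Reads lay between 49957257 and 59209652, while the deposited totals of the knockdown libraries all exceeded those of wild type.

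In the values as deposited, 9402 genes passed an adjusted p of 0.05 in limma, 9086 higher and 316 lower in the knockdown, so that 96.6% of the calls were higher. After TMM rescaling 7614 passed, 3063 higher and 4551 lower, so that 40.2% were higher. Across 5 scalings (as deposited, TMM, median of ratios, equal totals and quantiles), 2742 genes were higher under each of them and 316 were lower under each. These 316 are all the genes called lower as deposited, so the deposited shift set that number. The 2 counts therefore do not show that rises outnumber falls. A further 461 genes were called higher as deposited and lower after TMM. After TMM, 405 genes were at least 2-fold higher and 480 at least 2-fold lower. The values of the 2 groups did not overlap for 66.6% of genes as deposited and 61.1% after TMM. Chance gives 10% for any 1 gene, but all genes share the same 6 libraries, so these shares are not independent evidence. As deposited the median gene itself did not overlap: the highest wild type library was at 0.012 (replicate 3) and the lowest knockdown library at 0.136 (replicate 1). The deposited count rested on single libraries: it was 3723 without wild type replicate 1, 4286 without wild type replicate 2, 4854 without knockdown replicate 2 and 5153 without knockdown replicate 3. Of the 316 genes lower under each scaling, leaving out knockdown replicate 3 gave 206 and wild type replicate 1 gave 211. The standard error of the deposited fit had a median of 0.27 (0.211 at the 10% point and 0.279 at the 90% point), against a median of 0.08 after TMM. The common coefficient of variation between replicates was 0.226 at the deposited scaling and 0.0752 with TMM. The deposited fit had infinite prior degrees of freedom, against 10.32 after TMM, with 4 residual ones. It thus treated a library shift shared by all genes as a variance known from all genes. That shift was measured on only 6 libraries, so the deposited p-values and count of calls overstate the evidence.

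**Figure D2:**
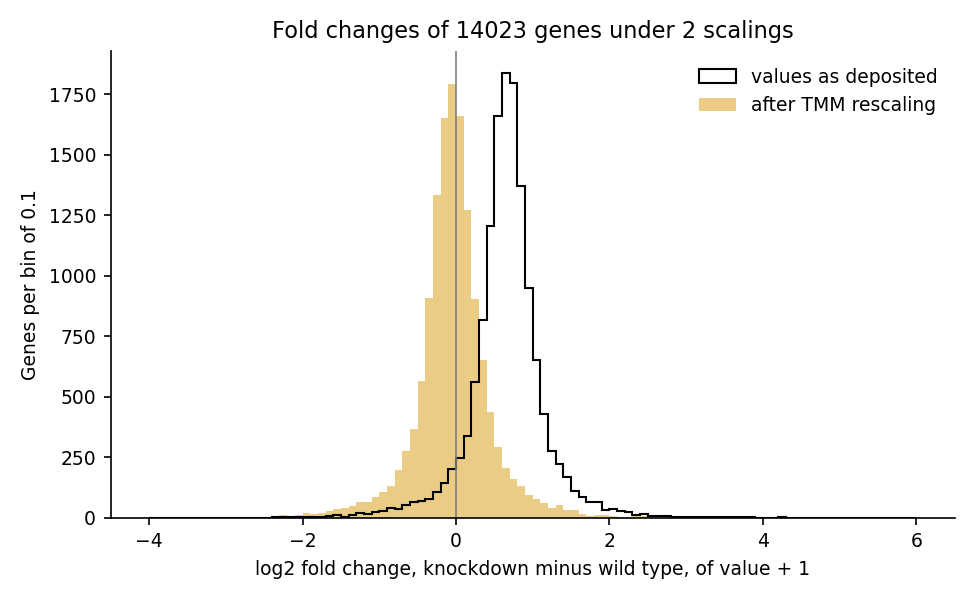
Number of genes by log2 fold change of value + 1, knockdown minus wild type, in bins of 0.1, for the 14023 genes tested. The outline (as deposited) centres on 0.67 and the filled histogram (after TMM) on -0.05.

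The 10 genes with the largest rise, ranked as deposited among genes with a mean of at least 5, included 4 globins: HBE1 (TMM log2 fold change 5.18, standard error 0.12), HBA2 (3.83, 0.08), HBG2 (3.61, 0.06) and HBA1 (3.49, 0.09), all with limma adjusted p of 9.27e-13 or less. HBA2 (chromosome 16, 172876 to 173710) and HBA1 (176680 to 177522) encode the same alpha globin, and HBG2 has a near-identical neighbour, so how reads were divided within each pair is uncertain. The annotated spans of HBE1 (chromosome 11, 5268345 to 5505652) and HBG2 (5253190 to 5505605) overlap, so reads in the shared part cannot be assigned with certainty either. CD2, a T and NK cell adhesion receptor (chromosome 1, 116754385 to 116769228), rose by 3.93 and RAP1GAP, which switches off the GTPase RAP1, by 3.60. HEPH, a copper-dependent iron oxidase, rose by 3.17, the calcium channel subunit gene CACNA2D3 by 3.21 and TRIM10, a gene of red cell development, 9.09-fold. HSPC324, annotated as an antisense gene (3.06), cannot be told from a gene on the other strand in libraries that do not record strand. All 10 were higher under each of the 5 scalings.

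The 10 genes with the largest fall, ranked as deposited among genes with a mean of at least 5, were led by DGKI, a diacylglycerol kinase (chromosome 7, 137381037 to 137847092), from 26.5 ± 4.52 to 2.38 ± 0.786 in deposited values (SD, n = 3 each; TMM log2 fold change -3.70, standard error 0.14, limma adjusted p = 4.66e-11). EPCAM, an epithelial adhesion molecule also found on early red cell progenitors, changed by -3.11, BDNF, a neurotrophin, by -3.10, and CALD1, an actin-binding protein, by -3.06. PCSK9, which directs the LDL receptor to degradation, changed by -3.00, TRAF5, a TNF receptor adaptor, by -2.88, and PRICKLE2, of planar cell polarity, by -2.78. CA2, a carbonic anhydrase of red cells, changed by -2.77, PDE5A, which breaks down cyclic GMP, by -2.71 and MAOB, a monoamine oxidase, by -2.69. All were lower under each of the 5 scalings, but so were all 316 genes called lower as deposited. The choice by deposited values thus fixed this outcome.

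Blood transcription factors fixed for report beforehand gave mixed results. TAL1 changed by 0.04 after TMM (limma adjusted p = 0.628), RUNX1 by 0.09 (adjusted p = 0.290) and MYC by 0.11 (adjusted p = 0.132), none past the threshold. As deposited the same genes were called higher, by 0.83, 0.87 and 0.90. GATA2 was lower by the TMM value of -0.54 (adjusted p = 1.78e-06) and not called as deposited (0.25, adjusted p = 0.382). STAT5A was called in opposite directions, -0.15 after TMM (adjusted p = 0.0245) and 0.64 as deposited (adjusted p = 0.0302). Of 36 transcription factors of haematopoietic stem cells, 13 rose and 17 fell after TMM (20 higher and 7 lower as deposited; adjusted over the list alone, 14 and 17 after TMM and 20 and 7 as deposited). NFIX rose 2.83-fold, TCF15 (log2 1.55), EGR1 (0.78) and MEIS1 (0.57) also rose, and the list did not pass the test against other genes (camera adjusted p = 0.0881 as deposited and 0.641 after TMM). Under each of the 5 scalings, 13 of the 36 were higher and 7 lower. Among the 7, and chosen after their values were seen, GFI1 changed by -1.94 after TMM, PBX1 by -1.91 and HOXA10 by -1.67.

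At the preset correlation 9 lists passed as deposited and 14 after TMM, while other splits of the 6 libraries gave up to 17 and up to 12. Of 30 erythroid genes tested, 21 rose and 6 fell after TMM, and 25 were higher and 1 lower as deposited, with the same counts adjusted over the list alone. The list stood 1.10 (log2) above other genes as deposited (camera adjusted p = 4.34e-20) and 1.03 after TMM (1.66e-07). Without near-identical globin and glycophorin copies it stood 0.51 above them as deposited (23 genes, camera adjusted p = 3.85e-04). With a correlation between genes estimated from the data the call of the whole list was lost (adjusted p = 0.985 as deposited and adjusted p = 0.340 after TMM with an estimated correlation). For each list, that test also has only 4 degrees of freedom. CA2, given above, was among those that fell.

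**Figure D3:**
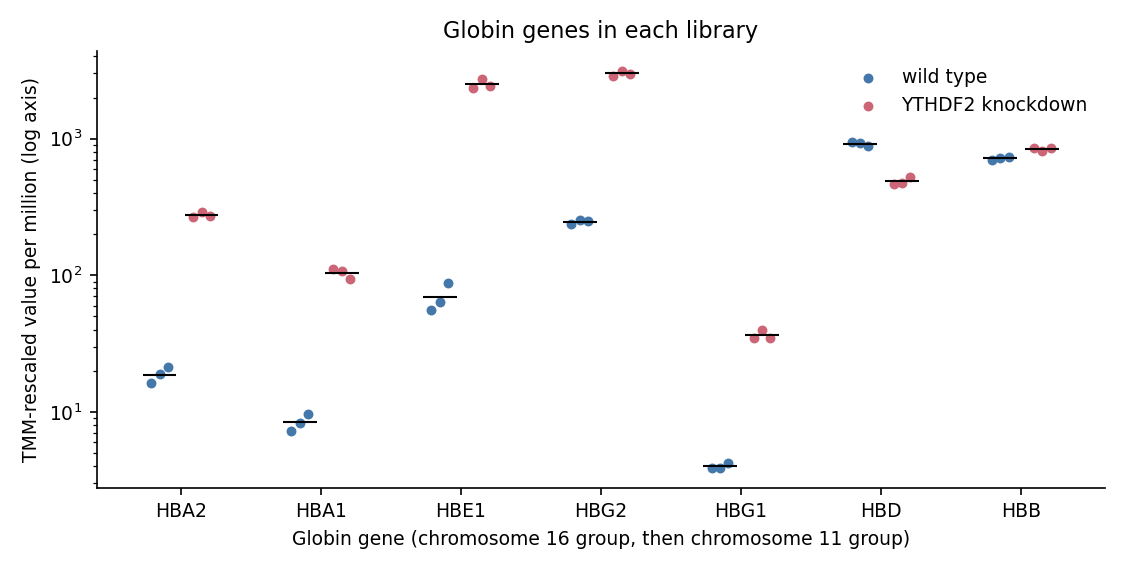
TMM-rescaled value per library (log axis) of the 7 globins of the erythroid list, alpha genes first; points are libraries, blue for wild type and red for knockdown, and bars are group means. HBE1 has group means of 69.1 and 2507; HBD is the exception, lower in the knockdown after TMM (-0.92) and not called as deposited (-0.12).

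Of 44 genes of the type I interferon response, 31 rose and 8 fell after TMM, and 36 were higher and 1 lower as deposited (adjusted over the list alone, 32 and 8 after TMM and 36 and 2 as deposited). RSAD2, an antiviral enzyme, rose by 2.83, MX1, an antiviral GTPase, by 2.67, IFI6 by 2.06 and IFI44L by 1.42. IFI44L had a deposited wild type mean of 0.24, so it passed the filter only through the knockdown libraries. The list stood 0.56 above other genes as deposited (camera adjusted p = 7.50e-09) and 0.57 after TMM (1.66e-07), with adjusted p = 0.997 as deposited and adjusted p = 0.340 after TMM with an estimated correlation.

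Of 31 p53 targets, 18 rose and 2 fell after TMM, and 29 were higher as deposited, with the same counts adjusted over the list alone. TRIM22 (1.27) and BTG2 (1.25), which are also interferon-responsive and immediate early genes respectively, GDF15 (1.01) and TNFRSF10C (0.83) rose. Of 2 members chosen after their values were seen, CDKN1A was called lower after TMM (-0.18, limma adjusted p = 0.0212). MDM2 was not called (-0.095, limma adjusted p = 0.163). As deposited both were called higher (0.61 and 0.69). The list stood above other genes (camera adjusted p = 0.00502 as deposited and 1.21e-04 after TMM), with adjusted p = 0.997 and adjusted p = 0.340 with an estimated correlation. Of 32 T and NK cell genes only 7 passed the filter, and of these 4 rose and 1 fell after TMM (6 and 1 as deposited, and the same adjusted over the list alone). They were led by CD2, GNLY, a cytotoxic granule protein (1.93), and GATA3 (1.20), with PRF1 at 0.37. GATA3 and PRF1 had deposited wild type means of 0.86 and 0.84, so they passed the filter only through the knockdown libraries. This list also stood above other genes (camera adjusted p = 1.53e-05 as deposited and 0.00831 after TMM), with adjusted p = 0.985 and adjusted p = 0.340 with an estimated correlation.

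Of 22 granulocyte genes, 18 fell and 3 rose after TMM, and 10 were lower and 3 higher as deposited, with the same counts adjusted over the list alone. DEFA4 (-2.71) and ELANE (-2.16), proteins of neutrophil granules, fell, BPI was called lower (-2.00) although the deposited values of its 2 groups overlapped, and LTF, lactoferrin, rose by 0.80. The list lay 1.04 below other genes after TMM (mean difference -1.04, camera adjusted p = 0.00244) and as deposited (mean difference -1.05, 2.44e-17), with adjusted p = 0.708 after TMM and adjusted p = 0.985 as deposited with an estimated correlation. Its mean log2 value also varied within groups, 4.26 ± 0.35 in wild type and 3.19 ± 0.46 in knockdown (SD, n = 3 each), far more than that of the mast cell list, 6.69 ± 0.06 and 5.80 ± 0.02. Of 21 genes of mast cells, basophils and eosinophils, 17 fell and 1 rose after TMM, and 6 were lower and 3 higher as deposited, with the same counts adjusted over the list alone. ENPP3 (-2.04) and HPGD, which inactivates prostaglandins (-1.91), fell, FCER1A, a chain of the IgE receptor, rose by 1.27, and CLC was at 0.25 (adjusted p = 0.318). The list lay below other genes (camera adjusted p = 9.25e-10 as deposited and 5.88e-07 after TMM), with adjusted p = 0.985 and adjusted p = 0.340 with an estimated correlation.

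Of 25 megakaryocyte and platelet genes, 16 fell and 3 rose after TMM, whereas 9 were higher and 2 lower as deposited, with the same counts adjusted over the list alone. TREML1, a platelet receptor, fell by 2.02, while F2RL2, a thrombin receptor (1.53), CMTM5 (0.47) and RAB27B (0.31) rose. The list lay below other genes (camera adjusted p = 0.0458 as deposited and 0.00653 after TMM), with adjusted p = 0.997 and adjusted p = 0.708 with an estimated correlation. The deposited call was lost without wild type replicate 1, knockdown replicate 1 or knockdown replicate 2, where the list's mean difference was -0.23, -0.21 and -0.25, and without the low-value filter that difference turned to 0.15. Of 17 Wnt pathway targets and feedback genes, 12 fell and 3 rose after TMM (5 lower and 6 higher as deposited; adjusted over the list alone, 12 and 3 after TMM and 5 and 5 as deposited). LEF1, a transcription factor of the pathway (-2.42), and TNFRSF19 (-2.20) fell, and CCND1, cyclin D1 (1.32), and RNF43 (0.96) rose. The list lay below other genes (camera adjusted p = 4.82e-04 as deposited and 0.00831 after TMM), with adjusted p = 0.997 and adjusted p = 0.340 with an estimated correlation, although its deposited median was 0.26 above 0. Of 34 replication-dependent histone genes, 23 fell and 1 rose after TMM, whereas 8 were higher and none lower as deposited (adjusted over the list alone, 23 and 1 after TMM and 2 higher as deposited). HIST1H3E rose by 0.25. The camera adjusted p was 2.00e-05 as deposited and 1.52e-04 after TMM, with adjusted p = 0.997 and adjusted p = 0.340 with an estimated correlation. The deposited median of this list, at 0.15, and of the megakaryocyte list, at 0.31, lay above 0 while the test against other genes was negative.

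**Figure D4:**
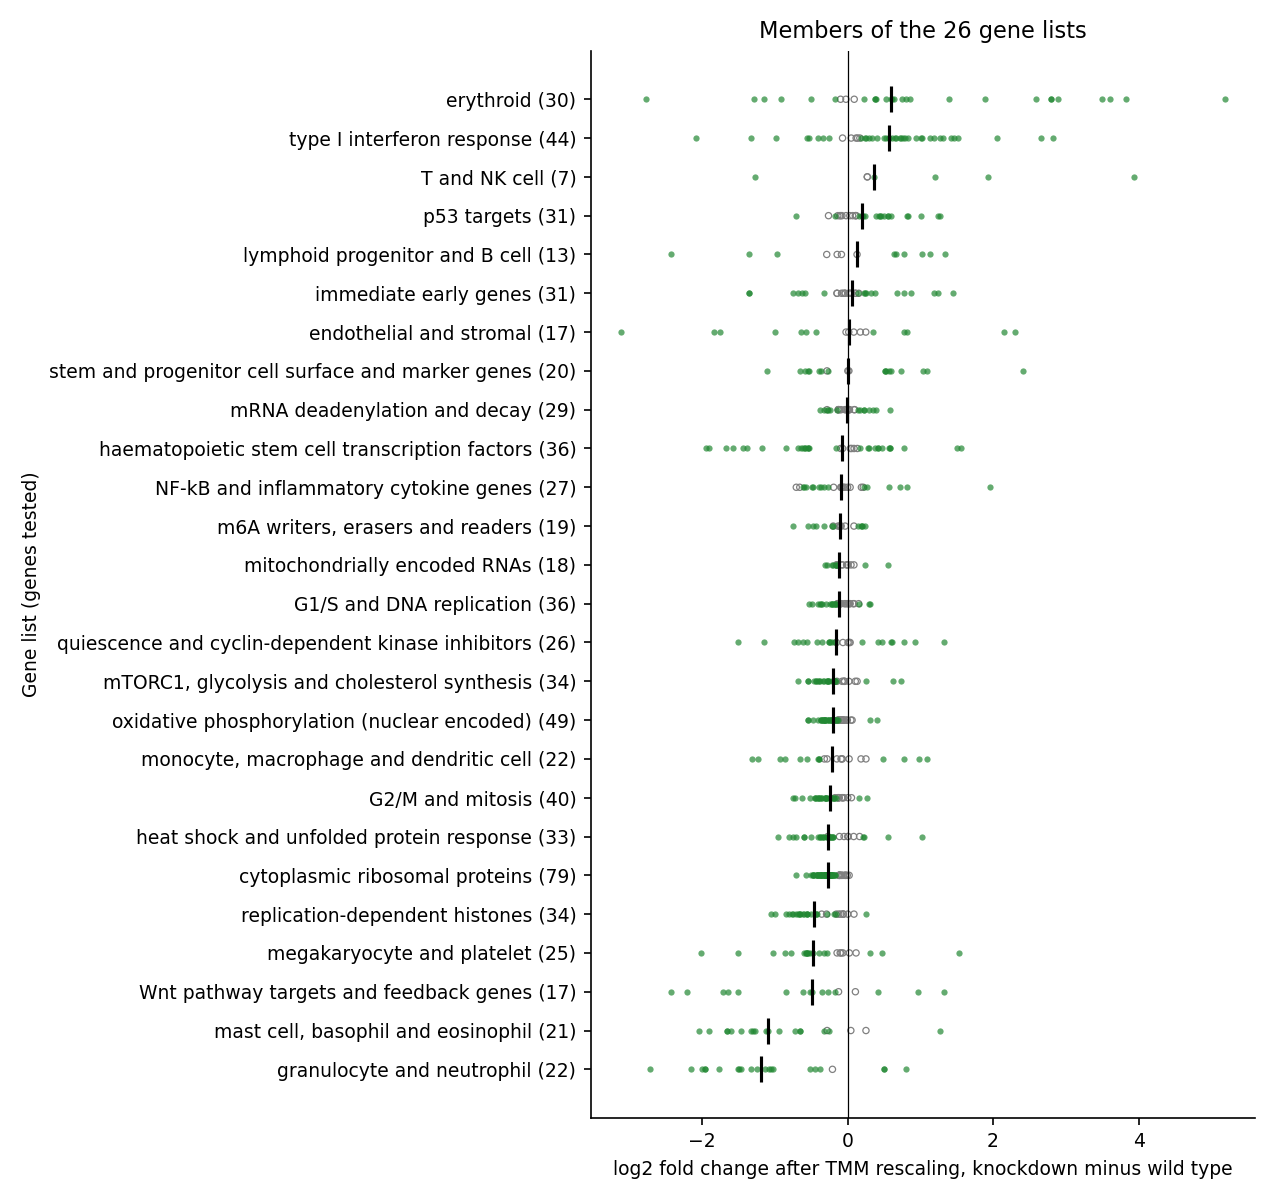
Each point is 1 gene of the list on the vertical axis, at its TMM-rescaled log2 fold change (knockdown minus wild type); filled green points passed an adjusted p of 0.05, open grey points did not, and the black bar is the list's median. Erythroid genes have the highest median (0.60) and granulocyte genes the lowest (-1.19); most points to the left of 0 by less than 0.67 lie above 0 as deposited.

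A set of 5 lists of housekeeping or growth genes passed the test against other genes after TMM and not as deposited. Of 79 cytoplasmic ribosomal protein genes, 65 fell and none rose after TMM, whereas 21 were higher as deposited (adjusted over the list alone, 65 fell after TMM and 0 were called as deposited; camera adjusted p = 3.85e-08 after TMM and 0.0667 as deposited). Of 40 G2/M and mitosis genes, 26 fell and 2 rose after TMM, and 18 were higher as deposited (adjusted over the list alone, 27 and 2 after TMM and 13 higher as deposited; camera adjusted p = 6.22e-04 and 0.230). TACC3 (0.27) and TPX2 (0.16), of the mitotic spindle, rose. Of 49 nuclear genes of oxidative phosphorylation, 32 fell and 2 rose after TMM, COX4I1 (0.40) and COX6B1 (0.31), and 27 were higher as deposited (adjusted over the list alone, 32 and 2 after TMM and 20 higher as deposited; camera adjusted p = 0.00119 and 0.505). Of 33 heat shock and unfolded protein response genes, 22 fell and 4 rose after TMM, VLDLR (1.02), SESN2 (0.55), MANF (0.22) and HSPA1A (0.21), and 11 were higher as deposited (adjusted over the list alone, 22 and 4 after TMM and 10 higher as deposited; camera adjusted p = 0.0120 and 0.232). Of 34 genes of mTORC1, glycolysis and cholesterol synthesis, 23 fell and 3 rose after TMM, SLC2A1 (0.74), SC5D (0.63) and SREBF1 (0.25), and 17 were higher as deposited (adjusted over the list alone, 23 and 4 after TMM and 10 higher as deposited; camera adjusted p = 0.0226 and 0.608). Without the low-value filter the deposited mean difference from other genes turned positive for oxidative phosphorylation (0.34) and mTORC1 genes (0.35). With an estimated correlation the calls of all 5 after TMM were lost (adjusted p = 0.708). As deposited, where none had passed, the adjusted p with an estimated correlation was 0.997.

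The other lists did not pass the test against other genes under either scaling, although most of their genes called as deposited were higher. Of 20 stem and progenitor cell markers, 9 rose and 8 fell after TMM (camera adjusted p = 0.327, and 0.230 as deposited), with rises in TEK, the angiopoietin receptor (2.41), ALDH1A1 (1.09), PROCR (1.03) and SELENOP (0.74). Of 17 endothelial and stromal genes, 5 rose and 7 fell (0.958, and 0.672), with the endothelial receptor KDR (2.30), the endothelial cadherin CDH5 (2.15) and the keratin gene KRT8 (0.77) higher and EPCAM lower. Of 19 m6A writers, erasers and readers, 5 rose and 7 fell (0.490, and 0.855); METTL14 (0.24), ALKBH5 (0.20), YTHDF1 (0.20) and VIRMA (0.18) rose, and without the low-value filter the list's deposited mean difference turned from -0.01 to 0.39. Of 29 genes of mRNA deadenylation and decay, 8 rose and 6 fell (0.682, and 0.648), with DCP1B at 0.58, RPP25 at 0.40, CNOT8 at 0.35 and PAN2 at 0.29. Of 22 monocyte and dendritic cell genes, 4 rose and 9 fell (0.682, and 0.232), and the 4 were CSF1R (1.09), CD4 (0.98), TLR4 (0.78) and CCR2 (0.49). Of 13 lymphoid progenitor and B cell genes, 6 rose and 3 fell (0.327, and 0.855), among them CD79A (1.34), LTB (1.13), CD79B (1.02) and LEF1 (-2.42). CD79A, SELENOP, KDR and CDH5 had deposited wild type means of 0.23, 0.42, 0.62 and 0.11. They passed the filter only through the knockdown libraries. Of 27 NF-kB and inflammatory cytokine genes, 6 rose and 9 fell (0.901, and 0.989), with CXCL8, interleukin 8, at 1.96, IL1B at 0.82, CCL2 at 0.73 and IRAK2 at 0.57. Of 31 immediate early genes, 12 rose and 7 fell (0.155, and 0.608), including DUSP5 (1.45), TRIB1 (1.18) and MAFF (0.87). Of 36 genes of G1/S and DNA replication, 3 rose and 15 fell (0.180, and 0.855), and the 3 were MCM7 (0.30), FEN1 (0.30) and TK1 (0.15). Of 26 genes of quiescence and kinase inhibition, 8 rose and 13 fell (0.755, and 0.989), with CCND1 (1.32), FOXO4 (0.93) and TXNIP (0.61) among those that rose. Of 18 mitochondrially encoded RNAs, 2 rose and 7 fell (0.682, and 0.989), the ribosomal RNAs MT-RNR1 (0.56) and MT-RNR2 (0.23) being the 2.

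As deposited, the genes called higher and lower in these 11 lists were 11 and 0 for stem and progenitor markers, 10 and 3 for endothelial and stromal genes, 11 and 0 for m6A genes, 23 and 0 for decay genes, 10 and 1 for monocyte and dendritic cell genes and 9 and 2 for lymphoid genes. They were 15 and 0 for NF-kB genes, 22 and 2 for immediate early genes, 26 and 0 for G1/S genes, 15 and 1 for quiescence genes and 14 and 0 for mitochondrial RNAs. Adjusted over the list alone, the counts after TMM were the same for stem and progenitor, endothelial, monocyte, lymphoid, NF-kB, immediate early, G1/S and mitochondrial genes, and were 5 and 8 for m6A genes, 7 and 5 for decay genes and 8 and 14 for quiescence genes. Mitochondrial reads took 2.05 ± 0.08% of reads in wild type and 2.21 ± 0.08% in knockdown, and the 10 highest genes of each library took 6.64 ± 0.05% and 6.11 ± 0.07% (SD, n = 3 each, exact permutation p = 0.1 for each, the smallest possible).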

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

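The count tests with their own scaling, the length and GC correction, all results after TMM that leave out a library or add a block, and the counts under each scaling were chosen after the data were seen. Of 550 results for single named genes across settings, 509 kept their direction and side of the threshold, 26 lost the call, 1 gained it and 14 reversed; for lists the numbers were 529, 20, 45 and 4. YTHDF2 stayed lower in each setting, between -2.73 and -1.70. Except where the construction shows it, the cause was not tested.

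Against 9086 higher and 316 lower genes as deposited, rescaling gave 3063 and 4551 (TMM), 2911 and 4378 (median of ratios), 4580 and 3188 (equal totals) and 3734 and 3832 (quantiles). The length and GC correction, which also centres each library, gave 3983 and 3645, edgeR with TMM on reads 3007 and 4578, and DESeq2 with its own factors 3532 and 3845. The stricter filter, which tests fewer genes, gave 179 lower genes and array weights 759. Leaving out 1 library gave 3723 to 12194 changed genes, 3512 to 11917 higher and 206 to 292 lower; after TMM it gave 6484 to 7969 changed. The genes higher under each scaling ranged from 2333 to 3179 and the lower ones from 206 to 292.

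With the replicate block, 4955 genes changed, 4747 higher and 208 lower, and 7576 after TMM. Deviations of libraries with the same number correlated at 0.06, 0.04 and -0.15 (TMM -0.05, 0.10 and -0.13), and not every library correlated best with its own number, so the numbers were not taken to pair the libraries.

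Of the 26 lists, 9 passed as deposited (4 higher, 5 lower). With TMM, median of ratios and equal totals 14 passed, 10 of them lower, and 9 were lower with quantiles and with edgeR and TMM, 8 with the length and GC correction and with DESeq2's own factors. The length and GC correction also took away the call of 1 list, neither the erythroid nor the interferon one. Without the filter 16 passed, 13 higher and 3 lower; with an estimated correlation 0 passed, 0 higher and 0 lower. Fry gave 3 lists, 0 of them lower, but it tests against no change rather than against other genes, so on deposited values it leans to higher lists and is not comparable with the camera counts. Leaving out 1 library gave 8 to 10 lists, 4 of them higher and 4 to 6 lower. Without the filter, which adds many genes near 0 to the background, 4 lists reversed: m6A genes to 0.39, megakaryocyte genes to 0.15, mTORC1 genes to 0.35 and oxidative phosphorylation to 0.34.

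GATA2 reversed to -0.54 (TMM), -0.55 (median of ratios), -0.42 (equal totals), -0.41 (quantiles), -0.46 (length and GC), -0.54 (edgeR with TMM) and -0.49 (DESeq2), from 0.25. STAT5A reversed to -0.15, -0.16, -0.034, -0.010, -0.076, -0.16 and -0.097 in the same order, from 0.64. In simulation at the same depth, 0% of 1.5-fold changes were recovered at the deposited scaling and 76.1% after TMM. The simulated groups differed by no shared shift, so the deposited share does not describe calls made on the real deposited values. Most simulated genes were unchanged, which TMM assumes, so the TMM share does not test that assumption.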

Other observations

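The tests on scaling factors, depth, RNA per cell, red cell transcripts, the whole interferon list and the vector were chosen after the result was seen, and the length and GC correction was added after the data were seen; those on near-identical copies and other splits were not.

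The genes in this paragraph were chosen after their values were seen. After TMM the globin genes of the beta group moved apart, while those of the alpha group given here all rose. In the alpha group on chromosome 16, the embryonic zeta globin HBZ was 2.59 higher (log2, TMM), HBM 2.41 and HBQ1 1.10, each past an adjusted p of 0.05 in limma. HBZ and HBM had deposited wild type means of 0.885 and 0.25, so they passed the filter only through the knockdown libraries. In the beta group on chromosome 11, HBG1 was 2.90 higher, while the adult genes HBB and HBD stood at 0.23 and -0.92 (limma adjusted p = 0.00369 and 1.47e-08). As deposited HBD was at -0.12 and not called, and HBB at 1.02. BCL11A and ZBTB7A, repressors of gamma globin, stood at -0.08 and -0.12 after TMM, neither past the threshold (adjusted p = 0.425 and 0.152), but were called higher as deposited (0.66 and 0.63, adjusted p = 0.0303 and 0.0373), and KLF1, an activator of adult globin, at 0.61. MYB stood at -0.63, KIT, the receptor for stem cell factor, at -1.10 and GATA1 at -0.02 (adjusted p = 0.754); as deposited MYB and KIT were not called (0.16 and -0.31) and GATA1 was called higher (0.77).

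Most genes were higher in the knockdown as deposited, with the median gene up by 0.67 (log2). Depth does not account for it, since log2 total reads differed by -0.10, the knockdown libraries holding fewer. Nor do standard edgeR factors computed over the genes of the table, since the closest of 4 methods was still 0.668 (log2) away from the implied factor of a library. More RNA per cell in the knockdown stays open: the exact permutation p of the median gene was 0.1, the smallest possible, and the values used here hold no spike-in or cell number. A scaling to such a measure could give these factors, and so could an unrecorded scaling step.

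Embryonic and fetal globins rose with other erythroid genes. At the preset correlation near-identical copies are not the whole of it: without them the list still stood above other genes (camera adjusted p = 3.85e-04 over 23 genes), but by 0.51 in place of 1.10 (log2, as deposited), so the copies carry much of its mean. With an estimated correlation the whole list was not called (adjusted p = 0.985 as deposited and adjusted p = 0.340 after TMM), so this argues against the copies only at the preset one. The same holds for a length and GC trend, whose removal left the list past the threshold at the preset correlation (5.05e-07). Mature red cells, or their RNA carried over, would bring their abundant transcripts along and stay open: 15 red cell transcripts that are not duplicated globins had a median of 0.372 after TMM and 1.16 as deposited, on either side of the bound of 1. The deposited median holds the shift shared by all genes, 0.67 for the median gene, so its place above the bound decides nothing. After TMM the median lay under the bound, but single transcripts went both ways. After TMM HBD was lower and AHSP at 0.09 (limma adjusted p = 0.280) while EPB42 (1.89) and GYPC (1.19) rose, and a sort for CD34+ cells would remove mature red cells.

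More interferon-responsive genes rose than fell. Whether 1 response raised the whole list stays open, since 18.2% of it was lower after TMM and 2.27% as deposited. The deposited share cannot decide this, because the shift shared by all genes left few calls in that direction. Of all 14023 genes tested, 316 were called lower as deposited and 4551 after TMM. BST2, chosen after its values were seen, was lower under both (-2.09 after TMM and -1.34 as deposited), while IFITM1 and IFITM3 were lower after TMM (-1.33 and -0.99) and not called as deposited. At the preset correlation length and GC content do not account for the rise, which held after that trend was removed (camera adjusted p = 2.74e-06), but with an estimated correlation the list was not called (adjusted p = 0.997 as deposited and adjusted p = 0.340 after TMM). A response to the vector cannot be told apart from one to loss of YTHDF2, because the labels give 1 knockdown group. They also do not say whether wild type cells carried a vector, although cells were sorted for green fluorescent protein. This limit holds for each difference between the groups. The interferon list lay 0.560 (log2) above other genes as deposited.

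With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split gave 9402 changed genes as deposited, where 1 of the 10 splits gave as many and the highest other gave 1, and 7614 after TMM, where 1 of 10 gave as many and the highest other gave 0. For lists after TMM the real split gave 14, 1 of 10 gave as many and the highest other gave 12. For lists as deposited the real split gave 9, all 10 splits gave as many and the highest other gave 17, so a count of lists at the preset correlation says little about the groups.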
